A study of Mus musculus with 6 samples.

How the data were processed

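Small RNA libraries of exosomes from bone marrow-derived macrophage supernatants were analysed for 3 WT and 3 Roquin-1 san:san samples, whose groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was harvested with Trizol and miRNA libraries were made by standard Illumina procedures. The same labels also name an mRNA library kit. The genome build was mm9, per the submitters' processing notes. The aligner, adapter trimming, read filters and miRNA annotation release are not given in the sources used here.

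The authors deposited a table of whole-number counts per mature miRNA for the series and, for each sample, a column of values named TPM. The deposited per-sample columns summed to between 1056890 and 1082573, more than TPM values can, so they were treated as a scaled signal. Each value above 0 was a whole multiple, within 0.1 reads, of the value of 1 read in its library (100% of values), and the recovered reads equalled the table's counts except for 1 miRNA in WT replicate 2. The read total that the scaling implies was between 92.4% and 94.6% of the table's total in the same library. Several near-identical miRNAs had identical counts in all 6 libraries, so a read that matches several names was counted for each of them, and 11 names were removed when such rows were merged. The number of columns from samples outside this series was 0.

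The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts of the 6 libraries, with filterByExpr at its minimum count of 10, TMM scaling, robust dispersions, genotype as the only term and Benjamini-Hochberg adjustment over the 254 miRNAs kept. These held between 98.2% and 99.3% of each library's counts. Means and SDs are of TMM-scaled CPM over 3 libraries. The miRNAs named in the text followed a rule fixed before the data were examined: up to 15 raised and 15 lowered with the smallest adjusted p, the 10 with the highest mean CPM, the arms of miR-146a, miR-101 and miR-142a with miR-155-5p, miR-223-3p and miR-21a-5p, up to 4 members of each list with the smallest p (3 were taken), and 5 hairpins of the arm test. Further members of short lists, minor arms and partner arms were named after their values were seen.

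A total of 22 miRNA lists were fixed before the data were examined: macrophage and myeloid, Toll-like receptor-induced, IL-4-associated, Roquin-linked, 8 seed families or clusters (let-7, miR-17~92 with paralogs, miR-15/16, miR-232724, miR-29, miR-30, miR-181, and miR-10 with miR-99, miR-100 and miR-125), the Dlk1-Dio3 and Sfmbt2 clusters, and markers of stromal, endothelial, epithelial, muscle, erythroid, lymphocyte, neural, and liver and gut cells. The 16 lists with at least 3 tested members entered camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists, with the estimated correlation and fry as alternatives. Lists overlap in a few members, such as miR-342-3p and miR-223-3p on both the myeloid and the IL-4 list. The Dlk1-Dio3 and Sfmbt2 lists are genomic. The GENCODE annotation of GRCm38 was used for hairpin GC content and the RefSeq annotation of GRCm38 for neighbourhood. Neither was used for coordinates of the authors' reads.

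For the arm comparison, log2 of the 5p over the 3p count, each plus 1, was tested with limma for hairpins with at least 20 counts over both arms in every library. The shares of counts were compared by two-sided exact permutation tests, which with 3 against 3 cannot give a p under 0.1. Ratios for miRNAs with 1 to 3 counts in a genotype carry exact 95% counting intervals.

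The procedures were tested on simulated negative binomial counts with the library sizes of these samples. Each miRNA had its mean share over all 6 libraries, and all miRNAs had a common dispersion of 0.0334. Differences in dispersion between miRNAs or genotypes were not simulated, so error rates may be higher in these samples. For this comparison, over an average of 259.5 tested miRNAs per run, edgeR called 61.0% of 2-fold changes, 93.9% of 4-fold changes and 0.986% of unchanged miRNAs. Camera found a planted list in 100% of runs and called 1.33% of the other lists among 254 miRNAs. The counts were drawn independently for each miRNA and the lists at random, so these camera rates do not cover lists of correlated miRNAs. The arm test found 78.6% of 4-fold changes among 49 hairpins but called 17.7% of unchanged hairpins, because a fixed pseudocount acts unequally on libraries of unequal depth. With a pseudocount in proportion to library size it found 67.9% and called 0.924%. With at least 10 counts of each arm in each genotype as well, it found 91.9% and called 1.65% of the hairpins that it still tested. Changed hairpins that this filter removed are not counted as missed, so the 91.9% cannot be compared with the other rates.

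Alternatives fixed before the data were examined were RLE factors, total counts, TMMwsp, library sizes without the 5 most abundant miRNAs, no filter, a filter at 10 CPM, DESeq2 1.42.0, limma-voom, non-robust dispersions, an FDR of 0.1, the recovered reads, summed arms, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were libraries thinned to the smallest total (21 draws), identical rows merged, an offset for hairpin GC content, and the scaled pseudocounts. Each pair of libraries of 1 genotype differed by more than counting noise, which repeat libraries of 1 sample could also do, so whether the samples are separate was not settled and all 6 were kept as labelled. Across libraries the correlation of log2 values was 0.888 to 0.944 within WT, 0.983 to 0.990 within san:san and 0.614 to 0.686 between genotypes, computed across miRNAs, which are not independent replicates.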

Results

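The series profiled the microRNAs (miRNAs) carried by exosomes, small vesicles released by cells, from the supernatants of bone marrow-derived macrophages. The macrophages came from 3 wild-type (WT) samples and 3 samples with the Roquin-1 san:san genotype, all on the C57BL/6 background. Roquin-1 is an RNA-binding protein that recognises stem-loops in messenger RNAs and promotes their decay, and san is the sanroque allele of its gene. The comparison asks how the miRNA content of macrophage exosomes differs with this genotype. The labels do not say whether replicates came from separate mice or cultures, so the p-values measure the spread between these samples, which may be technical.

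The WT libraries held 12447, 28884 and 21754 miRNA counts, and the san:san libraries 185901, 160588 and 126098. Every san:san library was therefore deeper than every WT library. Of the 707 miRNAs in the table, 337, 460 and 428 had at least 1 count in the WT libraries, against 520, 499 and 465 in the san:san libraries. A single count was worth between 34.6 and 80.3 CPM (counts of a miRNA scaled to a fixed library total) in WT and between 5.38 and 7.93 CPM in san:san. A miRNA with 0 counts could thus have reached 241 CPM in the shallowest WT library, taking 3 counts as the limit that a count of 0 allows. Such limits and counting intervals cover counting error only.

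**Figure D1:**
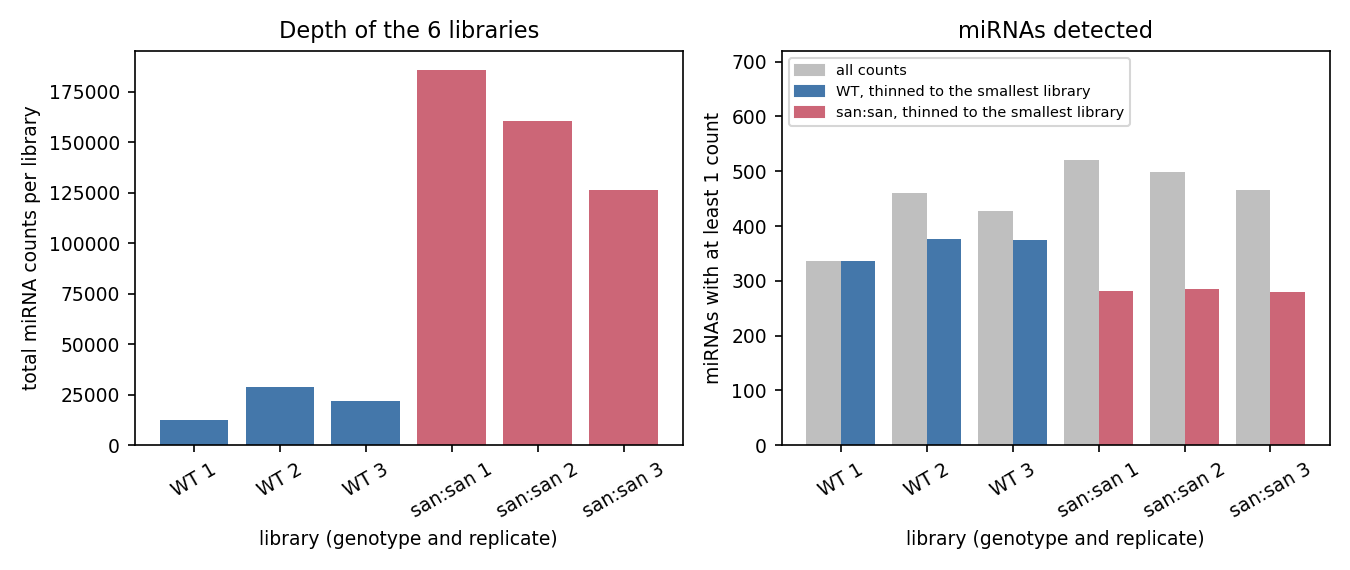
Left, total miRNA counts in each of the 6 libraries (bars, WT in blue and san:san in red). Right, the number of miRNAs with at least 1 count in each library before (grey) and after (coloured) thinning to the 12447 counts of the smallest library, where WT libraries kept 337, 376 and 374 miRNAs and san:san libraries 282, 285 and 280.

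In relative counts with TMM scaling, the san:san exosome libraries held more of several blood-cell miRNAs. They held less of 75 miRNAs, miR-23a-5p, miR-130a-3p and miR-196a-5p among them. Relative counts do not give the amount of a miRNA per exosome. miR-486a-5p, an erythroid miRNA whose counts are identical to those of miR-486b-5p, rose 5.67-fold, from 12176 ± 1712 to 69304 ± 7868 TMM-scaled CPM (SD, n = 3 per genotype throughout). miR-142a-3p, a miRNA of blood cells in general, rose 6.28-fold, and the lymphocyte miRNA miR-150-5p 5.49-fold. miR-130a-3p was 18.2-fold lower, at 36868 ± 8220 CPM in WT and 2016 ± 498 CPM in san:san. miR-23a-5p was 73.4-fold lower, at 16956 ± 2157 against 234 ± 68.6 CPM.

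Of 254 miRNAs that passed the filter on low counts, 163 differed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 88 higher and 75 lower in san:san, and 91 did not pass. The changes reached at least 2-fold for 74 of the higher and 69 of the lower miRNAs. This split depended on the scaling of the libraries, which moved the median log2 fold change of the tested miRNAs from 0.30 with TMM to 0.04 with RLE factors, 0.11 with DESeq2 and -0.30 with total counts. The same libraries gave 76 higher and 86 lower with RLE factors, 73 and 89 with library sizes that left out the 5 most abundant miRNAs, 62 and 104 with DESeq2, and 49 and 101 with total counts. In libraries thinned to the smallest total, which left a median of 131 miRNAs to test, 83 passed.

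**Figure D2:**
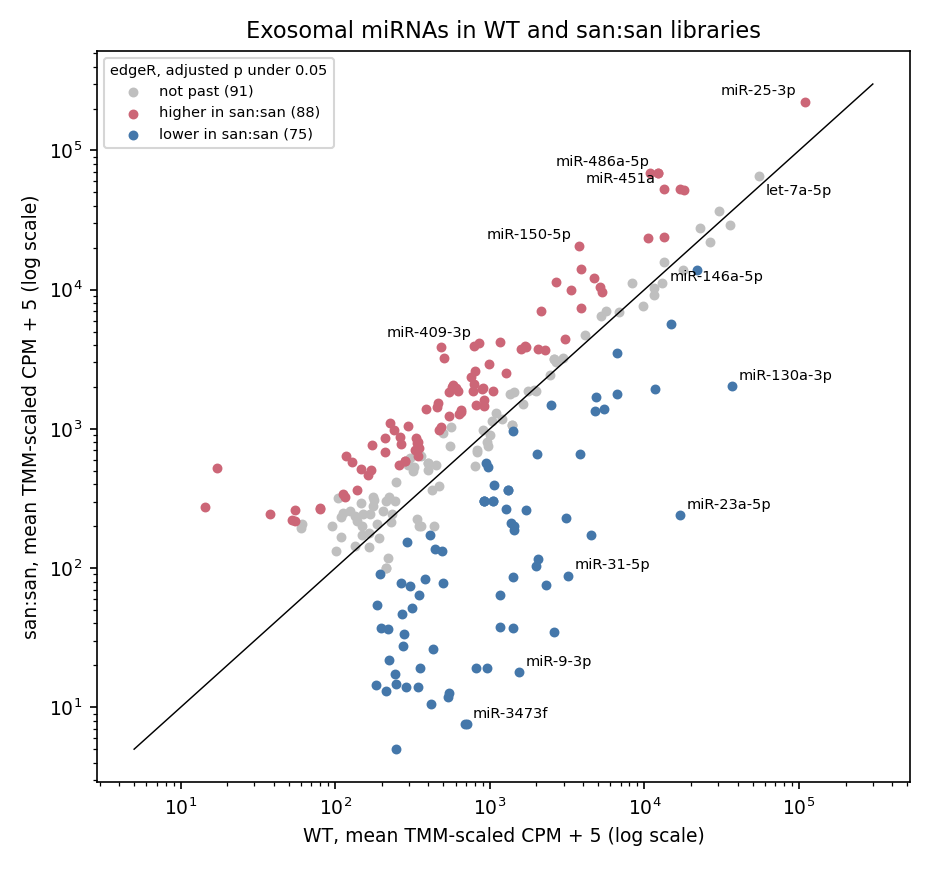
Mean TMM-scaled CPM of the 254 tested miRNAs in WT (horizontal) and san:san (vertical) libraries, both plus 5 and on log scales, with 3 libraries per genotype. Red points were higher and blue points lower in san:san at an adjusted p under 0.05 (edgeR), grey points did not pass, and the line marks equal values. With total counts in place of TMM, 49 in place of 88 were higher.

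The most abundant miRNA in all 6 libraries was miR-25-3p, of the miR-106b~25 cluster, with 1660, 3673 and 2903 counts in WT and 30924, 28214 and 25068 in san:san. It rose 2.06-fold (log2 1.04 ± 0.19, SE, edgeR adjusted p = 2.41e-04). Others among the 10 most abundant that rose were miR-451a (log2 1.97), miR-93-5p (1.63) and miR-126a-5p (1.55), besides miR-142a-3p and both miR-486 names. Values for let-7a-5p (log2 0.24, adjusted p = 0.294), let-7f-5p (-0.29, 0.254) and miR-92a-3p (0.28, 0.182) did not pass, and those of let-7a-5p and miR-92a-3p turned negative with total counts (-0.34 and -0.31). The call of let-7f-5p depended on the scaling, since it was lower with RLE factors (-0.55, 0.0463), total counts (-0.87, 0.00250), library sizes without the 5 most abundant miRNAs (-0.54, 0.0300) and in thinned libraries (-0.60, 0.0191). The calls for the miRNAs with the smallest adjusted p on the raised side also included miR-301a-3p (log2 3.12 ± 0.39, adjusted p = 1.07e-05), miR-1306-5p (2.70 ± 0.28, 2.32e-06), miR-574-3p (1.72 ± 0.20, 5.98e-06) and miR-505-3p (1.86 ± 0.25, 1.77e-05). On the lowered side they included miR-365-2-5p, which fell by 5.06 ± 0.30 on the log2 scale (adjusted p = 1.94e-08), miR-31-5p (by 38.1-fold), miR-196a-5p (25.9-fold) and its relative miR-196b-5p (18.3-fold), and miR-193a-5p (19.5-fold). Also lower were miR-5128 (91.4-fold), miR-3473b (40.9-fold), miR-3473e (35.7-fold), miR-706 (18.3-fold) and miR-690 (6.03-fold). miR-3473f had 54 counts over the WT libraries and 1 over the san:san libraries, a ratio of scaled counts of 269 with a 95% exact counting interval of 46.3 to 10832.

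miRNAs tied to Roquin in earlier work, miR-146a and miR-101, did not pass the test. miR-146a-5p, a brake on Toll-like receptor signalling, was at 13290 ± 4832 CPM in WT and 15732 ± 1891 CPM in san:san (log2 0.26 ± 0.25, edgeR adjusted p = 0.363). Its value was -0.32 with total counts, and without WT replicate 1 it was 0.49 with an adjusted p of 0.0288. miR-101a-3p stood at log2 0.52 ± 0.33 (adjusted p = 0.179) and miR-101c, with nearly the same counts, at 0.50 ± 0.33 (0.195), and both were below 0 with total counts (-0.09 and -0.11). None of the 3 tested members of this list passed, either over all miRNAs or adjusted over the list alone. miR-101b-3p, with 13 counts over WT and 13 over san:san, passed the count filter with a WT library left out, and was then lower without WT replicate 1 (log2 -2.44, adjusted p = 0.0121) or 2 (-2.86, 0.0118) but did not pass without WT replicate 3 (-1.55, 0.184). miR-155-5p, induced by inflammatory signals in macrophages, had 1, 7 and 1 counts in WT and 15, 13 and 3 in san:san and was too low to test, as were miR-101a-5p and, with all 6 libraries, miR-101b-3p. The level of the Roquin-1 messenger RNA was not analysed here.

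Macrophage and myeloid miRNAs were more often higher than lower in san:san: 6 of 9 tested members rose, none fell and 3 did not pass, and the count was 6 adjusted over the list alone. miR-142a-3p rose by log2 2.65 ± 0.33 (edgeR adjusted p = 1.12e-05), miR-342-3p by 1.87 ± 0.22 (5.91e-06) and miR-21a-5p by 1.15 ± 0.21 (3.19e-04). miR-223-3p, abundant in granulocytes and monocytes, rose by 0.87 ± 0.26 (adjusted p = 0.00849) and miR-142a-5p by 0.96 ± 0.24 (0.00339). Both calls ended without WT replicate 2 (0.128 and 0.0628) and with total counts (0.355 and 0.192). The call of miR-22-3p, also counted as raised, ended with RLE factors (0.266), TMMwsp (0.0860) and library sizes without the 5 most abundant miRNAs (0.244). It turned to log2 -0.025 with total counts, and was also lost without WT replicates 2 or 3 or san:san replicates 1 or 3. The list made up 5.50% ± 0.483 of WT counts and 11.0% ± 0.769 of san:san counts. Most of this rise in share came from miR-142a-3p, a miRNA of blood cells in general. It had 86, 354 and 455 counts in WT and 8260, 8290 and 8826 in san:san. As a set the list did not pass in camera (adjusted p = 0.101, or 0.575 with an estimated correlation), except with the replicate number as a block (0.0481). With total counts 3 of its members were higher and 1 lower, and with a library left out 4 to 7 were higher and 0 lower.

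Markers of other cell types moved with the genotype as well. Erythroid miRNAs made up 5.26% ± 1.26 of all counts in WT and 16.5% ± 1.24 in san:san, without overlap between the genotypes (exact permutation p = 0.1, the smallest that 3 against 3 allows, two-sided). Both miR-486 names hold the same reads, and with identical rows merged the shares were 3.88% ± 1.03 and 11.6% ± 1.01, with 3 of 4 tested higher. Of the 5 names tested, 4 were higher, also adjusted over the list alone and under every scaling: both miR-486 names, miR-451a (3.91-fold) and miR-144-5p (log2 1.33), while miR-144-3p did not pass (0.67, edgeR adjusted p = 0.158). The list passed in camera with its preset correlation (adjusted p = 0.0118), had an adjusted p = 0.575 with an estimated correlation, and did not pass once identical rows were merged (0.0881). The single tested lymphocyte miRNA, miR-150-5p, rose from 3795 ± 433 to 20672 ± 2474 CPM. Both tested endothelial miRNAs, miR-126a-3p (4.49-fold) and miR-126a-5p (2.92-fold), rose, and all 3 calls held adjusted over their lists alone. The endothelial share, 2.47% ± 1.05 in WT and 5.20% ± 1.80 in san:san, overlapped between genotypes (exact permutation p = 0.2). It was 3.69% in WT replicate 1 and 3.37% in san:san replicate 3. Of 4 liver and gut miRNAs, 3 were higher, also adjusted over the list alone (miR-192-5p log2 1.09, miR-194-5p 1.59 and miR-122-3p, with 2 counts over WT and 90 over san:san, a WT to san:san ratio of scaled counts of 0.111 and a 95% counting interval of 0.0132 to 0.412), while the far more abundant miR-122-5p did not pass (0.33, adjusted p = 0.186). With total counts 1 of these 4 was higher, and the camera test gave an adjusted p of 0.358. Stromal and smooth muscle miRNAs split, with 3 of 9 higher (miR-199b-5p 1.77, miR-199a-5p 0.78, miR-140-3p 0.87), 1 lower (miR-214-3p -0.81) and the same numbers adjusted over the list alone (camera adjusted p = 0.475). These depended on the scaling, with 1 higher and 2 lower with total counts and 1 and 1 with DESeq2: the miR-199a-5p call was lost with RLE factors (adjusted p = 0.0679), DESeq2 (0.0870), total counts (0.546) and without WT replicate 2 (0.0636), and the miR-140-3p call with DESeq2 (0.0589), total counts (0.437) and without san:san replicate 3 (0.0563), and both were lost without the 5 most abundant miRNAs in the library sizes and in thinned libraries. Without WT replicate 2 the list had 2 higher and 0 lower (miR-214-3p -0.63, adjusted p = 0.111), and without WT replicate 3 it had 5 higher and 1 lower. Of 2 neural miRNAs miR-128-3p rose (1.16) and miR-219a-5p fell (-2.48), both also adjusted over the list alone, but the miR-128-3p call was lost with total counts (0.55, adjusted p = 0.115) and in thinned libraries (0.103), and miR-219a-5p, with 17 counts over WT and 15 over san:san, fell below the count filter without any 1 of the san:san libraries. Epithelial miRNAs held 0.0257% ± 0.0134 of WT counts and 0.0144% ± 0.00214 of san:san counts, and skeletal and heart muscle miRNAs 0.0104% ± 0.0180 and 0.00743% ± 0.00224, with 0 members of either list deep enough to test.

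miRNAs of the imprinted Dlk1-Dio3 region, a large cluster on chromosome 12 in the GRCm38 annotation, were higher in san:san. Of 32 tested members 21 rose, none fell and 11 did not pass, and the numbers were the same adjusted over the list alone. Examples were miR-409-3p (log2 2.27 ± 0.23, edgeR adjusted p = 1.51e-06), miR-127-3p (2.38 ± 0.32, 2.12e-05) and miR-487b-3p (1.78 ± 0.25, 2.80e-05). The median change was 1.22, which lay 0.92 above the median of all tested miRNAs. The list passed in camera with the preset correlation (adjusted p = 0.00810), had an adjusted p = 0.575 with an estimated correlation, and did not pass in thinned libraries (0.138), which left 9 members to test, 6 of them higher. The number of higher members was 8 with total counts, 9 with DESeq2, 14 with library sizes that left out the 5 most abundant miRNAs and 10 without WT replicate 2, with 0 lower each time.

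The miRNAs encoded in an intron of Sfmbt2 on chromosome 2, many of them near-identical copies, were lower in san:san. Of 14 tested names 12 fell and 2 did not pass, also adjusted over the list alone. They held 1.38% ± 0.183 of WT counts and 0.272% ± 0.0368 of san:san counts (exact permutation p = 0.1). These shares count some reads under several names. With identical rows merged they were 0.840% ± 0.130 and 0.162% ± 0.0233, with 8 of 9 tested names lower. miR-669a-3p and miR-669o-3p fell by 1.99 ± 0.31 on the log2 scale (edgeR adjusted p = 8.98e-05) and miR-466a-3p by 1.72 ± 0.29 (1.49e-04), values that are uncertain for single members because 1 read can match several names. The list passed in camera with the preset correlation (adjusted p = 0.0280) and had an adjusted p = 0.575 with an estimated correlation. It also lost the call once identical rows were merged (0.0914), without san:san replicate 1 (0.0638) and in thinned libraries (0.147, with 7 members tested, all lower).

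**Figure D3:**
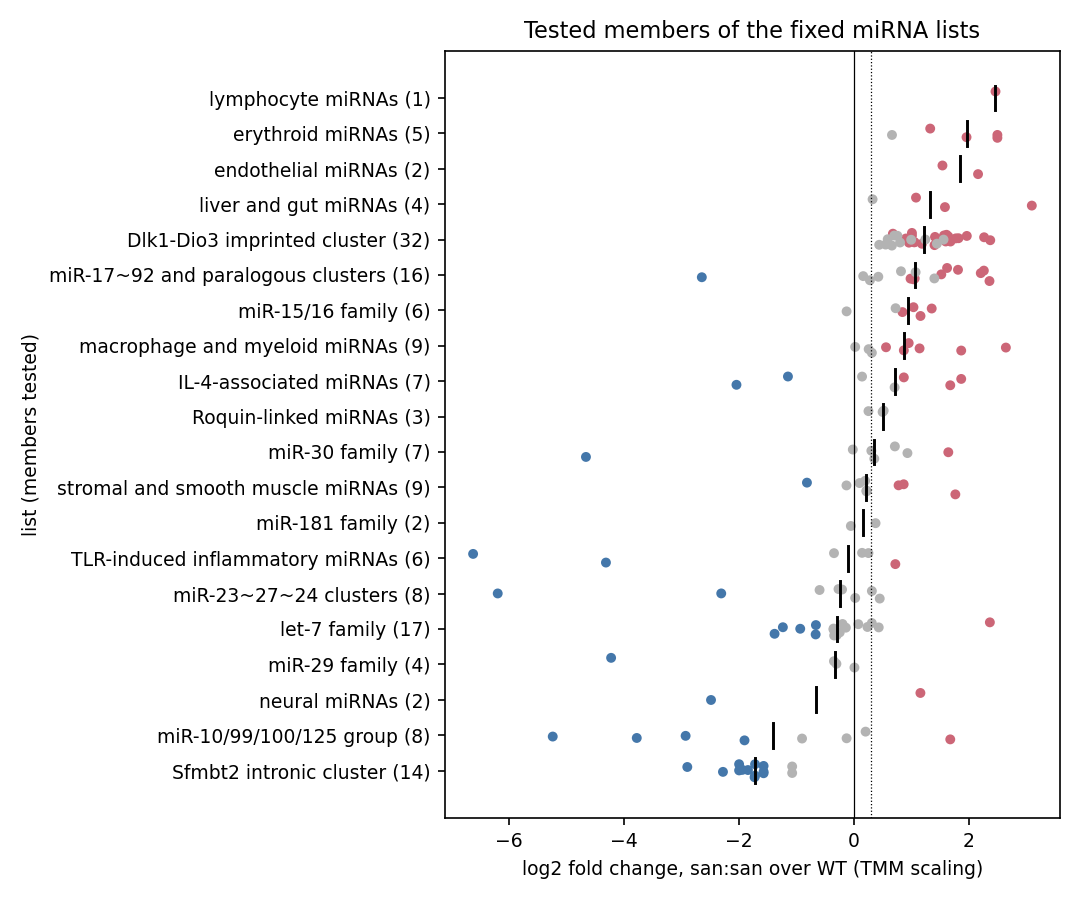
Log2 fold change (san:san over WT, TMM scaling) of each tested member of the fixed miRNA lists, with 1 point per miRNA (red higher, blue lower at an adjusted p under 0.05 in edgeR, grey not past), black ticks at list medians, a solid line at 0 and a dotted line at the median of all tested miRNAs, 0.30. All 32 Dlk1-Dio3 points lie above 0 and all 14 Sfmbt2 points below it, while with total counts the median of all tested miRNAs moves to -0.30.

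The miR-17~92 cluster and its paralogs, which promote cell proliferation, were mostly higher, with 9 of 16 raised, 1 lowered and 6 not past, and the same numbers adjusted over the list alone. miR-19a-3p rose by log2 2.21 ± 0.31 (edgeR adjusted p = 2.83e-05), miR-106b-3p by 1.82 ± 0.24 (2.19e-05) and miR-18a-3p by 2.27 ± 0.38 (1.59e-04), whereas miR-25-5p, the minor arm of the miR-25 hairpin, fell by 2.64. The camera test gave an adjusted p of 0.0678, or 0.575 with an estimated correlation, and the list passed without WT replicate 3 (0.0222) and with the replicate number as a block (0.0308). With total counts 6 were higher and 1 lower. let-7 miRNAs, which repress growth and cell-cycle genes, made up 22.3% ± 2.13 of all counts in WT and 13.5% ± 1.26 in san:san, without overlap (exact permutation p = 0.1). Of 17 tested names 5 fell, 1 rose and 11 did not pass, and adjusted over the list alone 3 fell and 1 rose. The lowered members included let-7c-5p (log2 -1.38 ± 0.19, adjusted p = 2.87e-05), let-7e-5p (-0.93 ± 0.20, 0.00114) and let-7b-5p (-0.66), and the raised one was miR-98-3p (2.37 ± 0.36, 6.63e-05). miR-98-3p had 11 counts over WT and 289 over san:san and was too low to test in most thinned draws. Its partner arm miR-98-5p did not pass (0.08). The family's median was -0.29, 0.59 below that of all tested miRNAs, its camera test gave an adjusted p of 0.659, and 11 were lower with total counts, 7 with RLE factors and 3 without WT replicate 2, with 1 higher each time.

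The miR-10, miR-99, miR-100 and miR-125 group had 4 of 8 members lower and 1 higher, also adjusted over the list alone. miR-125a-3p (log2 -3.78 ± 0.23, edgeR adjusted p = 1.94e-08), miR-99b-3p (-2.93 ± 0.29, 1.67e-06) and miR-125b-5p, a regulator of blood cell differentiation (-1.90 ± 0.20, 2.32e-06), fell. The other lowered name, miR-125b-1-3p, had 28 counts over WT and 3 over san:san. Only miR-125b-5p among the lowered names was a 5p arm, and miR-125a-5p (0.21) and miR-99b-5p (-0.12) did not pass with TMM scaling. The raised member, miR-99a-5p, had 5 counts over WT and 79 over san:san and did not pass with RLE factors, total counts or DESeq2, nor without WT replicates 1 or 3, and the set's camera adjusted p was 0.0701. With total counts 6 of the group were lower. In the miR-232724 clusters, 2 of 8 were lower, also adjusted over the list alone, namely miR-23a-5p and miR-23b-5p (-2.31), while their partner arms miR-23a-3p (-0.26, adjusted p = 0.305) and miR-23b-3p (-0.20, 0.441) did not pass (camera adjusted p = 0.358). The miR-23b-5p call rests on 13 counts over WT and 13 over san:san, it fell below the count filter without any 1 of the san:san libraries, and the miR-23b arm ratio did not pass with the scaled pseudocount (limma adjusted p = 0.0970). With total counts 6 of the 8 were lower, with RLE factors 3, and without WT replicate 1, where 10 were tested, 4. Of the 6 tested miRNAs on the list of Toll-like receptor-induced miRNAs, 2 were lower, miR-9-3p (98.8-fold) and miR-9-5p (19.9-fold), and 1 was higher, miR-222-3p (log2 0.73 ± 0.28, adjusted p = 0.0383), with the same numbers adjusted over the list alone (camera adjusted p = 0.448). Both lowered names are arms of miR-9, and miR-9-5p, with 35 counts over WT and 8 over san:san, was too low to test in most thinned draws. The miR-222-3p call was lost without WT replicates 1 or 3, without san:san replicates 1 or 3, and with every other scaling tried, while miR-146a-5p, miR-146b-5p (0.15, 0.530) and miR-221-3p (-0.34, 0.164) did not pass, although miR-221-3p was lower with RLE factors (-0.60, 0.0210), total counts (-0.95, 0.00154) and without WT replicate 1 (-0.57, 0.00675).

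The arms of a hairpin did not always change together. For the miR-23a hairpin the ratio of 5p to 3p counts fell by 5.44 ± 0.33 on the log2 scale, from 273, 531 and 457 counts of the 5p arm beside 468, 940 and 540 of the 3p arm in WT to 28, 28 and 30 beside 3785, 2995 and 1808 in san:san (limma adjusted p = 1.16e-05). The miR-125a ratio moved the other way, by 3.50 ± 0.22 (1.16e-05), as miR-125a-5p did not pass (0.21, edgeR adjusted p = 0.337) while miR-125a-3p fell. The ratios of miR-99b (2.26 ± 0.31, limma adjusted p = 8.21e-04) and miR-130b (3.42 ± 0.54, 0.00178) also moved to 5p, and those of miR-25 (-2.39 ± 0.22, 1.12e-04) and miR-98 (-1.86 ± 0.21, 3.07e-04) to 3p. miR-25-5p had 5, 10 and 8 counts in WT and 9, 4 and 5 in san:san, where the pseudocount exceeded each count. The size and SE of the miR-25 ratio thus rest largely on the pseudocount. miR-98-3p had 4, 4 and 3 counts in WT. The ratios use a pseudocount in proportion to library size and hairpins with at least 10 counts of each arm in each genotype, a version chosen after seeing the data. In this version 13 of 25 hairpins passed, 6 toward 5p and 7 toward 3p in san:san.

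The version fixed beforehand, with a pseudocount of 1 in every library, passed 24 of 49 hairpins, 13 toward 5p and 11 toward 3p. On simulated counts of these depths it also called 17.7% of unchanged hairpins. The later version called 1.65% of the unchanged hairpins that it still tested. In the fixed version the smallest p-values belonged to miR-23a, miR-328, miR-150, miR-125a and miR-486a. For miR-328 the 5p arm had 17, 18 and 20 counts in WT and 3, 3 and 0 in san:san, where the 3p arm had 13, 20 and 10 and 273, 268 and 172. miR-150-3p had 0, 1 and 0 counts in WT and 0 in every san:san library, and miR-486a-3p 0, 5 and 0 against 0, so the ratios of these hairpins were set by depth and their major arm.

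**Figure D4:**
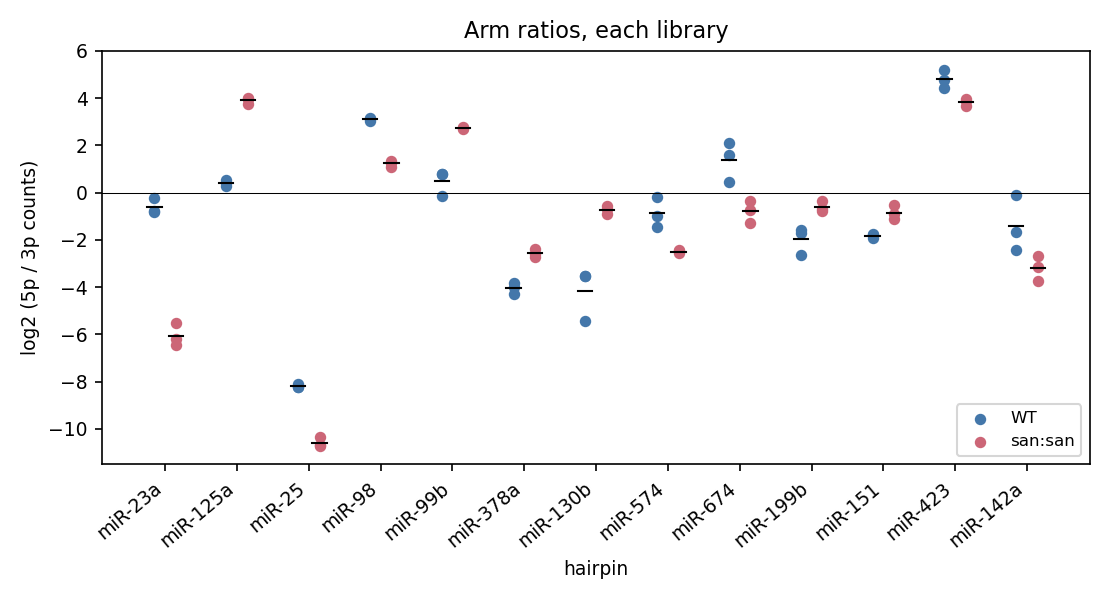
Log2 ratio of 5p to 3p counts in each library (points, WT in blue and san:san in red, 3 libraries each, black ticks at means) for the 13 hairpins with an adjusted p under 0.05 (limma), with a pseudocount in proportion to library size. The miR-23a ratio averages -0.61 in WT and -6.06 in san:san, and the miR-125a ratio 0.40 and 3.90.

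Counts were more concentrated in the san:san libraries. The 10 most abundant miRNAs of each library held 45.9% ± 2.95 of counts in WT and 58.3% ± 2.22 in san:san, a difference of 12.4 percentage points, and miR-25-3p alone held 13.1% ± 0.360 and 18.0% ± 1.67, each without overlap between genotypes (exact permutation p = 0.1). With identical rows merged, the 10 most abundant held 47.1% ± 2.83 in WT and 58.4% ± 2.01 in san:san, a difference of 11.3 points. In libraries thinned to 12447 counts, 362 ± 22 miRNAs had a count in WT and 282 ± 2.52 in san:san (exact permutation p = 0.1). At full depth the number of miRNAs with at least 10 CPM was 408 ± 63.8 and 410 ± 21.4 (exact permutation p = 1), a measure that depth sets, because 1 count already exceeds 10 CPM in every WT library.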

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

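The thinned libraries, merged rows, GC offset and scaled pseudocounts were chosen after seeing the data, and the others before. Of the 163 called miRNAs, 151 kept call and sign with RLE factors, 135 with DESeq2, 124 with total counts, 159 with the GC offset, 77 in thinned libraries (where a median of 93 were still tested) and at least 126 with any single library left out. Leaving out a library gave 134 to 175 calls, 69 to 91 higher and 62 to 89 lower, with 2 to 4 lists, 17 to 25 hairpins and a difference in the share of the 10 most abundant miRNAs of 11.2 to 14.1 points. No called miRNA named by the fixed rule changed sign under any alternative run. Total counts gave 49 higher miRNAs, and thinned libraries 83 calls, 39 higher and 45 lower (medians of 21 draws), with fewer miRNAs tested and fewer counts. Counts past the threshold without a filter (207) and with the filter at 10 CPM (205) rose with the number tested.

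Lists past the threshold numbered 3 with camera, 0 with an estimated correlation, 12 with fry and 15 with its mixed test (neither of which compares a list with other miRNAs), 1 with identical rows merged and 1 in thinned libraries, where adjusted p was 0.138 for Dlk1-Dio3 and 0.147 for Sfmbt2. Hairpins numbered 12 with at least 100 counts, 32 with a pseudocount of 5, 28 with a scaled pseudocount, 13 with the scaled pseudocount and at least 10 counts per arm (10 to 15 with a library left out), and 13 in thinned libraries.

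The cause of changes of sign was not tested beyond the shift of scale. A miRNA outside the fixed rule, miR-22-3p, was called higher with TMM scaling but stood at log2 -0.025 with total counts (edgeR adjusted p = 0.936). Among the miRNAs named by the rule and the share measures, values that changed sign belonged to measures that had not passed. With total counts these were miR-101a-3p (log2 -0.086), miR-101c (-0.11), miR-92a-3p (-0.31), miR-181a-5p (-0.22), let-7a-5p (-0.34) and miR-146a-5p (-0.32). In thinned libraries they were miR-92a-3p (-0.048), miR-181a-5p (-0.10), let-7a-5p (-0.094) and miR-146a-5p (-0.086), and let-7a-5p was -0.016 with RLE factors and -0.0076 without the 5 most abundant miRNAs in the library sizes. miR-181b-5p was 0.094 without a filter, 0.056 with the filter at 10 CPM, 0.037 with limma-voom and between -0.41 and 0.25 with a library left out. The share of the most abundant miRNA differed by -0.12 points once miR-25-3p was left out. The number of miRNAs with at least 10 CPM differed by 1.33, by -34.3 to 27.2 with a library left out and, counted as miRNAs with a count, by -80.0 in thinned libraries.

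The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.10, -0.08 and 0.26, and 1 of 3 WT libraries matched its own number best. With the replicate block 161 miRNAs, 5 lists and 21 hairpins passed. Depth limits the WT side most, since miRNAs under about 241 CPM can be missed in the smallest WT library.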

Other observations

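The tests of depth, scaling and genomic clusters below were chosen only after the results were seen. The remaining fixed lists gave mixed pictures. Of 6 tested miR-15/16 miRNAs, which restrain the cell cycle, 4 rose (miR-15b-3p log2 1.16, miR-322-5p 1.36, miR-16-5p 0.85, miR-15b-5p 1.04), also adjusted over the list alone, with 2 higher under total counts and a camera adjusted p of 0.258. With any 1 library left out miR-497a-5p (50 counts over WT and 42 over san:san) also passed the count filter and was lower, for example by 2.37 on the log2 scale without san:san replicate 1 (adjusted p = 0.00300). Of 7 miRNAs linked to IL-4 activation of macrophages, miR-342-3p, miR-223-3p and miR-99a-5p rose and both miR-378a arms fell (miR-378a-3p -2.04), also adjusted over the list alone (camera adjusted p = 0.516), with 1 higher and 2 lower under total counts, 2 and 1 with DESeq2, and 1 and 1 in thinned libraries. In the miR-29 and miR-30 families the members that fell with TMM scaling were minor arms, miR-29b-1-5p (18.7-fold) and miR-30c-1-3p (25.3-fold), 1 of 4 and 1 of 7 tested, while miR-30c-5p rose 3.13-fold (edgeR adjusted p = 2.87e-05), with the same numbers adjusted over each list alone and camera adjusted p of 0.446 and 0.657. With total counts all 4 miR-29 miRNAs were lower, and the abundant arm miR-29a-3p was lower with RLE factors (-0.60, adjusted p = 0.0183), total counts (-0.93, 7.80e-04), DESeq2 (-0.50, 0.0166), library sizes without the 5 most abundant miRNAs (-0.60, 0.0103), thinned libraries (-0.62, 0.0206) and the GC offset (-0.53, 0.0267). Neither tested miR-181 miRNA passed, also adjusted over the list alone (miR-181a-5p 0.38, adjusted p = 0.281, and miR-181b-5p -0.05, 0.918), but miR-181a-5p was higher without WT replicate 1 (0.68, 0.0265).

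Most tested miRNAs differed between the genotypes, in libraries whose depth also differed with genotype. In libraries thinned to the smallest total, 93 of the 163 called miRNAs were still tested (medians of 21 draws throughout). Of these 100% kept their sign (lowest draw 98.9%), with a median size 93.0% of that at full depth. Thinning keeps each miRNA's expected share of its library, so sign and size were nearly fixed in advance and do not test depth. At equal depth 77 were still called, which argues against unequal numbers of counts alone as the source of those calls. Of the 69 called miRNAs that were tested in at most 10 of the 21 draws, 11 had more counts in every WT library than in every san:san library (exact binomial test of equal counts, Bonferroni p under 0.05), such as miR-3473f with 54 against 1, which deeper san:san libraries alone cannot produce. The other 58 were too low to test after thinning, and for them the number of counts cannot be told apart from the genotype. TMM scaling and hairpin GC content as the whole cause are argued against by the 124 calls that kept call and sign under total counts and the 159 that did so after a GC offset. The slope of log2 CPM per 10% of hairpin GC did differ with genotype. It was 0.0646, 0.134 and 0.0664 in WT and -0.0534, -0.0927 and -0.119 in san:san. The offset used GC of hairpins, so it does not cover a bias set by the mature sequence. A difference in RNA input, vesicle purity or library preparation that goes with the depth gap may still contribute, and stays open beside the genotype itself, because no library breaks the link between depth and genotype.

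With TMM scaling, most tested erythroid names (4 of 5, or 3 of 4 with identical rows merged) and Dlk1-Dio3 miRNAs (21 of 32) were higher in san:san. Of the 32 Dlk1-Dio3 miRNAs, 15 were higher with RLE factors, 9 with DESeq2 and 8 with total counts. Both lists had a camera adjusted p of 0.575 with an estimated correlation. RNA from a source other than the macrophages is not excluded as an explanation. For bovine serum in the medium as the source, the test cannot tell it apart from a mouse source: 0 rodent-only Dlk1-Dio3 miRNAs passed the count filter, and the 1 such row in the table had 0 counts in WT and 2 in san:san. The labels do not say whether serum was used. Red blood cells, a mixed blood-cell source and a change in the macrophages with the genotype were not tested and stay open.

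The log2 fold changes of miRNAs from hairpins within 10 kb of each other spread somewhat less than those of miRNAs put together at random, which may reflect shared primary transcripts. Every tested name was placed at each of its hairpins, and the Dlk1-Dio3 and Sfmbt2 regions were left out. Names of 1 cluster that share reads were merged (such as miR-486a-5p with miR-486b-5p and miR-374b-5p with miR-374c-5p). Names in different clusters were not merged, so let-7a-1-3p and let-7c-2-3p, each with 103 counts over WT and 408 over san:san, were counted separately. The mean within-cluster SD was 1.05 over 84 miRNAs in 28 clusters, against 1.28 when the values were permuted over the names (permutation p = 0.0171, 10000 permutations). Single members still differed widely, such as miR-23a-5p (log2 -6.20) beside miR-23a-3p (-0.26), miR-30c-1-3p (-4.66) beside miR-30e-3p (0.31), miR-29b-1-5p (-4.22) beside miR-29a-3p (-0.34), and miR-351-5p (-2.10) beside miR-322-5p (1.36), examples chosen after their values were seen. The pattern was tested on the same libraries in which it was looked for, and it does not separate a source in macrophages from one in other cells.

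With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For called miRNAs the real split gave 163 and the highest other 0, so 1 of the 10 gave as many. For hairpins the values were 24 and 0, again 1 of 10. For lists the real split gave 3 and the highest other 5, and 8 of the 10 splits gave at least as many.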
